A study of Mus musculus with 18 samples.

How the data were processed

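RNA was sequenced from 18 mouse libraries in 6 groups of 3, made from embryonic stem cells (ESCs), bone-marrow-derived macrophages and neuronal progenitor cells (NPCs). In each cell type 3 libraries came from untreated cells and 3 from cells treated with NVP-AUY922, an inhibitor of the chaperone HSP90. Per the labels' protocols, treatment lasted 24 h at 100 nM in ESCs, 500 nM in macrophages and 50 nM in NPCs. Per the labels, the ESCs and NPCs were of the 129S1/CASTEiJ background and the macrophages of the BALBC/C57BL6 background, so cell type, dose and, for macrophages, strain change together. The libraries were stranded, paired-end and poly(A)-selected, per the labels' protocols. Transcripts without a poly(A) tail, such as many SINE and structural RNA transcripts, are depleted by such a protocol. Nothing in the labels says that the replicates were separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

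The values analysed here are those of 3 tables of results that the authors deposited, 1 per cell type, each with 1365 repeat subfamilies over 6 columns. Each row is named by a repeat and its class, and stands for all genomic copies of that repeat together. Per the submitters' processing notes, which give no roles or order, Trim Galore, TopHat2 2.0.13, Bowtie2, featureCounts, DESeq2 and deepTools were used with genome build mm10. Per the file headers, the columns of the authors' deposited tables are those of a DESeq2 result. The base mean, a signal, is in such a table the mean over the libraries of read counts divided by size factors, computed by the authors. The log2 fold change and its standard error, also log2, are the authors' estimates for the contrast between the groups. The Wald statistic is a score the authors obtained from them, and it equalled the log2 fold change divided by the standard error in all 1132, 1255 and 1249 rows tested, within a relative difference of 1e-06. The p-value and adjusted p-value are those the authors deposited, and within the same tolerance all adjusted values equalled a Benjamini-Hochberg adjustment over the rows that carry one. How reads that fit several copies or several subfamilies were assigned, and whether strand was used in counting, is not given in the sources used here. Near-identical subfamilies, and a long terminal repeat (LTR) and the internal part it flanks (named with the ending -int), can therefore share reads. Reads of transcripts of genes that hold a repeat copy can also enter a row. The ESC and NPC libraries carry a CASTEiJ genome in part, and reads were placed on a reference of another strain.

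The tables do not say which group was the numerator of the contrast. The group labels in alphabetical order would put untreated cells in the denominator, so that a positive value would mean more RNA in treated cells, but nothing in the sources used here settles it. Values are therefore given as lying on the positive or the negative side of the authors' contrast, and no row is said to have gone up or down with treatment.

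Because the tables hold the authors' comparison and no values per library, the branch of the analysis plan for such tables was used in place of a count model. Main results are the authors' adjusted p under 0.05, with no standard deviation or n computed here. Rows with a base mean under 1 reached an absolute log2 fold change of at most 0.25 in ESCs, 0.42 in macrophages and 0.37 in NPCs. Values this small in rows with so few reads point to fold changes that were shrunken towards 0. So does the standard error of 0.34 for MLT1J1-int in macrophages, at a base mean of 1.6. The sources used here do not state it. Rows with low base means may thus lie nearer 0 than their reads alone would put them. This also bears on differences between tables in which the base means of a row are unlike. Adjusted p-values were given for 1132 rows in ESCs, 1255 in macrophages and 1249 in NPCs, and only these rows were tested. A p without an adjusted p was given for 209, 51 and 77 rows, in that order, and these stayed untested. A further 4 rows in ESCs, the satellites GSAT_MM, MurSAT1 and SYNREP_MM and the row C573_MM of the class Other, had a fold change and no p.

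Differences between cell types were computed here, per subfamily tested in both tables, as the difference of the log2 fold changes divided by the root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment. No library enters 2 cell types. This and the overlaps take the tables as oriented alike, which the sources used here do not state, so both were also computed with the sign of 1 table of each pair turned. Levels were never compared across tables, since each was normalised by itself. Overlaps of called subfamilies were tested per side with Fisher's exact test, two-sided, over the subfamilies tested in both tables. The same test compared the share of called subfamilies among LTR rows with that among LINE, SINE and DNA transposon rows. Relations between log2 fold changes of 2 tables used 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

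The analysis plan was fixed before the data were examined, and it included 15 lists of repeats defined by name. They are IAP, ETn/MusD, MERVK10C, RLTR9/13/17 enhancer-like LTRs, MERVL/MT2, ORR1 and MT MaLR, VL30, MLV-like and GLN, L1Md, older L1, SINE B1, SINE B2/B3/B4, DNA transposons, satellites and structural RNA repeats. By plan, the RLTR9/13/17 list also holds names starting with RLTR11 or BGLII. The SINE B2/B3/B4 list also holds ID elements. For each list the mean of log2 fold change over standard error was set against 100000 random lists of the same size drawn from the tested rows, two-sided, with Benjamini-Hochberg adjustment over the lists of a table. The smallest p this can give is 1e-05. Subfamilies are not independent replicates, and without values per library the correlation between members could not be estimated. Some name patterns took in more than was meant. The pattern for MLV-like elements also matched names from RLTR40 upwards, such as RLTR44, which are 28 of its 38 members. The pattern for L1Md also matched 6 older L1 rows, and that for DNA transposons took in 8 rows that are LTR elements by class. The pattern for satellites took in MurSatRep1, of the class Unknown. The lists were kept as fixed, and narrowed patterns were added as an alternative after the data were seen.

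Subfamilies are named by a rule fixed in advance: per cell type, among rows past adjusted p 0.05 with a base mean of at least 50 and leaving out simple and low-complexity repeats, the 10 with the largest and the 10 with the smallest log2 fold change. Another 18 names were to be given whatever their result, of which 15 have a row in the tables. The other 3, L1 names, match no row under that spelling. From each list the members with the smallest adjusted p are named as well. Repeat coordinates are not given here, since each row sums copies across the genome and no repeat annotation was used here.

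The depth of each library is not given in the sources used here. Summed over all rows, base means came to 3840470 normalised reads in ESCs, 1987974 in macrophages and 2084220 in NPCs. These totals show the mean normalised reads in repeats per library and not its depth. Precision differed between the tables: among tested rows with a base mean of at least 50, the median standard error of the log2 fold change was 0.11 in ESCs and in macrophages and 0.21 in NPCs. Below a base mean of 50 it was 0.30, 0.32 and 0.39. The procedure was tested on simulated data that kept the rows and standard errors of each table and none of its fold changes. In each run of the row test 200 changed rows were planted and all others set to no change. Errors were drawn as normal and independent between rows, so these shares do not cover related rows or fold changes shrunken towards 0. Changes of 0.5 on the log2 scale were called in 67.0% of rows with the ESC table, 61.0% with the macrophage table and 24.0% with the NPC table. For changes of 1 the shares were 98.0%, 85.0% and 78.0%. Differences of 1 between cell types were found in 80.5% of planted rows for ESCs against macrophages, 62.0% for ESCs against NPCs and 61.0% for macrophages against NPCs. Of the rows called in this 1 simulated draw per table, 0.60% were unchanged rows with the ESC table, 5.19% with the macrophage table and 7.27% with the NPC table. Among the differences found, the share of unchanged rows was 4.17% for ESCs against macrophages, 6.06% for ESCs against NPCs and 3.94% for macrophages against NPCs. In 40 simulated runs of the list test per table, lists with no planted shift had an unadjusted p under 0.05 in 5.71%, 4.82% and 4.64% of tests, in the order ESCs, macrophages and NPCs. Since these runs drew all rows as independent, shares near the threshold follow from the setting. They check the calculation and do not show how the test behaves on real lists, whose members can share reads.

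Alternatives covered the multiple-testing adjustment over every row with a p, a base mean minimum of 50, leaving out structural RNA and low-complexity rows, centring on the median row, and stricter thresholds. For the lists they covered the median in place of the mean, a base mean minimum, centring, and leaving out the member of largest absolute change. Random lists matched on base mean, the narrowed patterns and the turned sign were added after the data were seen.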

Results

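The study asked how inhibition of HSP90, a chaperone that assists the folding of many signalling and regulatory proteins, changes RNA from endogenous retroviruses and other repeats in mouse cells. Poly(A) RNA was sequenced from 18 libraries in 6 groups of 3: untreated and NVP-AUY922-treated embryonic stem cells (ESCs) grown in 2i medium, bone-marrow-derived macrophages and neuronal progenitor cells (NPCs). The inhibitor was given for 24 h at 100 nM to ESCs, 500 nM to macrophages and 50 nM to NPCs. What is reported are the values of the authors' deposited table for each cell type, which compares the 3 treated with the 3 untreated libraries over 1365 repeat subfamilies. A subfamily sums the reads of all its genomic copies. Errors after ± are standard errors (SE) of the log2 fold change from these tables. The tables do not state which group is the numerator, so a subfamily is described as lying on the positive or negative side of the contrast, and neither side is assigned to treated cells. Nor is it stated that the side means the same group in each table. The depth per library is not given in the sources used here; the median base mean over rows above 0, in normalised reads, was 126 in ESCs, 88.0 in macrophages and 104 in NPCs.

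In ESCs, elements of the MERVL family stood at the positive end and elements of the ETn/MusD family at the negative end. MERVL-int, the internal part of an ERVL retrovirus transcribed in the early mouse embryo, lay at 2.95 ± 0.08 in the authors' deposited table, a 7.73-fold difference between the groups, at a base mean of 53553. Its adjusted p was listed there at 0. MT2_Mm, the LTR of MERVL, lay at 2.34 ± 0.07, a 5.07-fold difference, with an adjusted p of 3.228e-245 in the authors' deposited table. On the other side, ETnERV-int and MMETn-int, internal parts of ERVK elements of the early transposon group, lay at -2.95 ± 0.10 and -2.93 ± 0.10 in the authors' deposited table. These are differences of 7.71-fold and 7.60-fold, at base means of 47472 and 81651. Of 1132 subfamilies tested in the authors' deposited table, 251 passed an adjusted p of 0.05, with 115 positive and 136 negative, and 356 had an unadjusted p under 0.05. Only 36 of the 251 lay beyond 1 on the log2 scale, 18 on each side. The median over tested rows was 0.0019 in ESCs, -0.0129 in macrophages and 0.0009 in NPCs. Which rows the size factors were taken from is not given in the sources used here. If these were the repeat rows, a shift common to most repeats would not show, and the balance of the sides would say little.

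The other ESC subfamilies that the naming rule selects on the positive side were again LTR elements. MER89, an ERV1 element, had the largest value in the authors' deposited table at 3.06 ± 0.10 (8.35-fold, base mean 2373). RLTR44D, RLTR44-int and RLTR44A, all ERVK, followed at 2.75 ± 0.17, 2.21 ± 0.09 and 1.42 ± 0.14 in the authors' deposited table. There, IAP1-MM_LTR and IAP1-MM_I-int lay at 1.41 ± 0.14 and 1.32 ± 0.09, MER54A at 1.23 ± 0.13 and RLTR19D at 1.18 ± 0.21 in the authors' deposited table. On the negative side the ERVK elements ERVB4_1C-LTR_Mm, RLTR13G and ERVB7_1-LTR_MM lay at -2.81 ± 0.10, -2.76 ± 0.10 and -2.54 ± 0.10 in the authors' deposited table. RNERVK23-int and RLTR30D_RN lay at -1.64 ± 0.15 and -1.60 ± 0.13, and RLTRETN_Mm, an LTR of the ETn group, at -1.59 ± 0.10 in the authors' deposited table. RLTR46A2 and RLTR46B, with base means of only 90.6 and 53.0, lay at -1.39 ± 0.20 and -1.30 ± 0.23 in the authors' deposited table. The adjusted p of these 16 subfamilies was at most 4.165e-07 in the authors' deposited table.

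**Figure D1:**
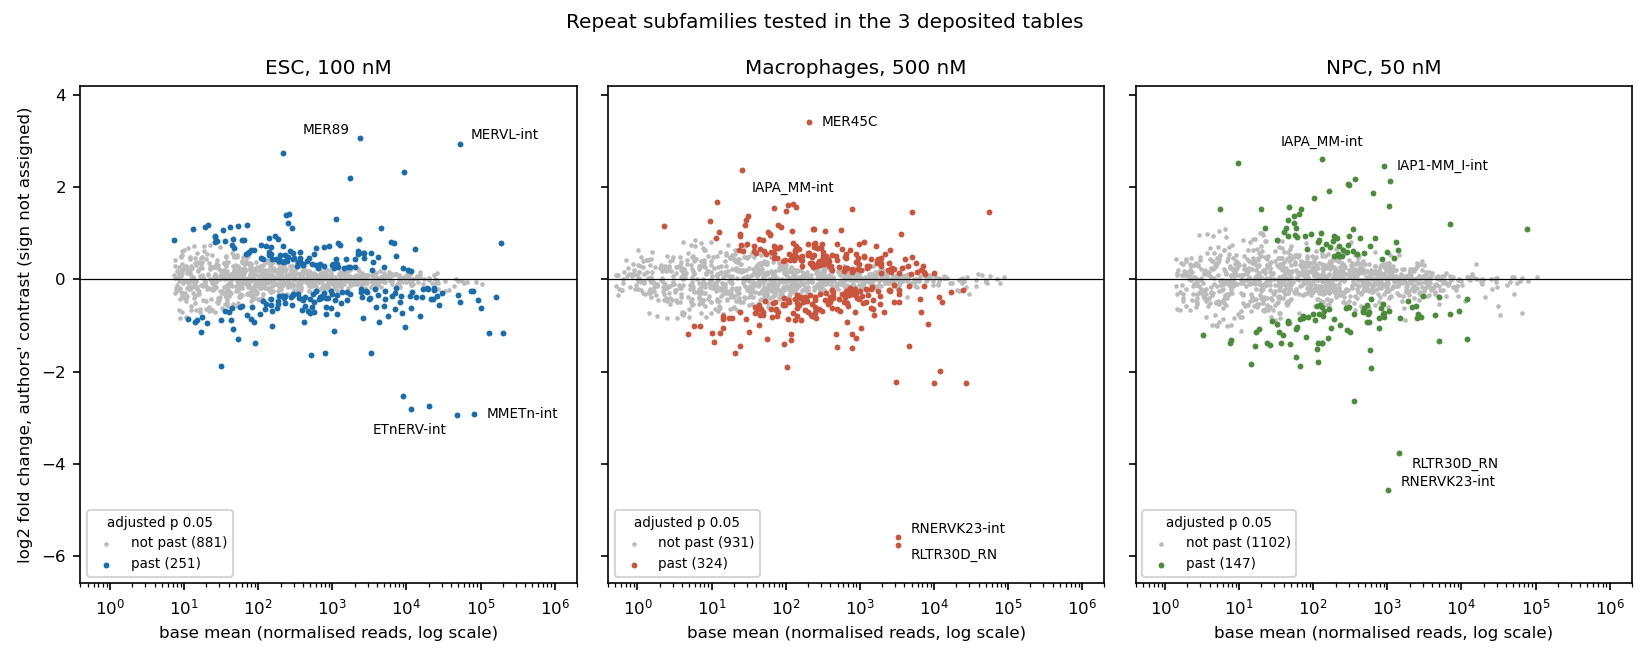
Log2 fold change of the authors' contrast (y axis, log2 units, sign not assigned to a group) against base mean (x axis, normalised reads, log scale) for every repeat subfamily tested, 1 panel per cell type with its inhibitor dose. Coloured points passed an adjusted p of 0.05 (251 in ESCs, 324 in macrophages, 147 in NPCs), grey points did not, and the 2 farthest named subfamilies on each side are labelled.

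Among the 15 lists fixed before the data were examined, 5 stood apart from random lists of tested ESC subfamilies (permutation test over 100000 random lists, adjusted over the lists). Of the 25 tested members of the IAP list, intracisternal A particles, which are ERVK elements still able to transpose in mice, 15 were positive, 1 negative and 9 not past the test. Adjusted over the list alone, 16 were positive and 2 negative. The list's median was 0.36 and its permutation adjusted p was 0.0009; IAPEz-int, the most abundant member at a base mean of 188716, lay at 0.80 ± 0.10 in the authors' deposited table (1.74-fold). Of the 10 ETn/MusD rows 9 were negative and 1 did not pass, also when adjusted over the list alone, with a median of -0.71 and a permutation adjusted p of 7.5e-05, from 1e-05, the smallest that these permutations can give. Of the 8 MERVL/MT2 rows 6 were positive and 2 did not pass, also adjusted over the list alone, with a median of 0.53 and a permutation adjusted p of 7.5e-05. Besides MERVL-int and MT2_Mm, MT2C_Mm lay at 0.88 ± 0.08 and MT2B2 at 0.57 ± 0.08 in the authors' deposited table. Subfamilies are not independent replicates, and reads may be shared between related rows.

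The other pair of lists past the test depended on a choice of setting. MERVK10C had 6 positive and 0 negative members of 13, the same counts adjusted over the list alone, with a median of 0.18 and a permutation adjusted p of 0.0428. RLTR10-int at 0.82 ± 0.07 and MMERVK10D3_I-int at 0.80 ± 0.10 had its smallest adjusted p in the authors' deposited table. The adjusted p of this list was 0.121 with medians in place of means, 0.0636 among rows with a base mean of at least 50, 0.146 without its member of largest absolute change, and 0.0655 against random lists matched on base mean; it was 0.0431 with centring. The RLTR9/13/17 list of LTRs named for enhancer-like activity also holds RLTR11 and BGLII names. Among these, BGLII lay at -0.83 ± 0.09 and RLTR11A at -0.61 ± 0.07 in the authors' deposited table. The whole list had 4 positive and 14 negative of 51, or 4 and 15 adjusted over the list alone, with a median of -0.08 and a permutation adjusted p of 0.010. Its adjusted p was 0.106 with medians in place of means and 0.0942 without RLTR13G, its member of largest absolute change, and between 0.00262 and 0.0225 under the other alternatives.

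The remaining 10 lists in ESCs did not pass, with permutation adjusted p between 0.189 and 0.856. ORR1 and MT MaLR had 4 positive and 10 negative of 96, VL30 1 and 1 of 5, MLV-like and GLN 8 and 11 of 36, L1Md 3 and 7 of 31, and older L1 5 and 8 of 99. SINE B1 had 0 and 2 of 15, SINE B2/B3/B4 0 and 3 of 12, DNA transposons 11 and 3 of 119, satellites 0 and 2 of 3, and structural RNA repeats 4 and 0 of 28. Adjusted over the list alone, none of these counts differed by more than 2. Of the 8 positive members of the MLV-like list, 6 were RLTR44 elements, which are ERVK and which the name pattern took in beside the viruses it was meant for. The list narrowed to those viruses after the data were seen had 1 positive and 4 negative of 10. MER54A, an ERVL element by class, had the smallest adjusted p of the DNA transposon list, which took it in by name, and Tigger16a, a DNA transposon, lay at 0.95 ± 0.16 in the authors' deposited table. Of the MaLR rows, ORR1A3-int lay at 1.12 ± 0.07 and ORR1A0-int at -0.62 ± 0.08 in the authors' deposited table. B2_Mm1t and B2_Mm1a, short interspersed elements with the base means 131775 and 200237, lay at -1.16 ± 0.19 and -1.17 ± 0.20 in the authors' deposited table. L1MdFanc_I lay at -0.55 ± 0.07 in the authors' deposited table. Of the satellite list, MurSatRep1, of the class Unknown, lay at -0.50 ± 0.07 and the satellite MMSAT4 at -0.35 ± 0.08 in the authors' deposited table. The median log2 fold change, the mean log2 fold change and the mean test value did not share a sign for ORR1 and MT MaLR, MLV-like and GLN, L1Md and structural RNA repeats.

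Of the subfamilies given whatever their result, IAPLTR1_Mm and IAPLTR2_Mm, LTRs of IAP elements, lay at 0.67 ± 0.10 and 0.45 ± 0.09 in ESCs in the authors' deposited table. MMVL30-int and MMERVK10C-int lay at 0.28 ± 0.08 and 0.26 ± 0.07, and ETnERV2-int at -0.93 ± 0.09 in the authors' deposited table. ORR1A0, B1_Mm and B2_Mm2 lay at -0.36 ± 0.09, -0.24 ± 0.07 and -0.45 ± 0.09 in the authors' deposited table, with adjusted p of 3.074e-04, 6.205e-03 and 1.469e-05. RLTR4_MM-int at 0.13 ± 0.09 and RLTR6_Mm at -0.10 ± 0.09 did not pass, with adjusted p of 0.349 and 0.466 in the authors' deposited table. GSAT_MM, the major satellite, had a value of -0.44 ± 0.29 and no p in the authors' deposited table, so that this value may rest on an extreme count.

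In macrophages, a pair of rows, RLTR30D_RN and RNERVK23-int, stood far apart from all others on the negative side. They lay at -5.76 ± 0.27 and -5.59 ± 0.29 in the authors' deposited table, differences of 54.1-fold and 48.3-fold at base means of 3267 and 3304. Elements related to murine leukaemia virus followed on this side, with RLTR4_Mm at -2.26 ± 0.15, RLTR4_MM-int at -2.26 ± 0.13 (4.78-fold, base mean 27268) and MuLV-int at -1.997 ± 0.109 in the authors' deposited table. On the positive side, MER45C, a DNA transposon, lay at 3.41 ± 0.17 (10.7-fold, base mean 206) in the authors' deposited table. IAPEz-int at a base mean of 55687 and its LTR IAPLTR1_Mm both lay at 1.45, with SE 0.14 and 0.15 and a 2.74-fold difference each, in the authors' deposited table. Of 1255 subfamilies tested there 324 passed, 167 positive and 157 negative, and 436 had an unadjusted p under 0.05. Beyond 1 on the log2 scale lay 53, of which 25 were positive and 28 negative.

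The further macrophage subfamilies under the naming rule lay closer together. IAPA_MM-int, an IAP element, lay at 1.64 ± 0.20 in the authors' deposited table, the ERVL elements LTR101_Mam and LTR41B at 1.63 ± 0.22 and 1.57 ± 0.15, and X7C_LINE, a CR1 element, at 1.54 ± 0.18. MERVK26-int lay at 1.53 ± 0.14, the DNA transposon Kanga1 at 1.49 ± 0.19 and ERVB4_3-I_MM at 1.18 ± 0.21 in the authors' deposited table. RLTR11A lay at -2.22 ± 0.14 (4.66-fold), SRV_MM-int at -1.89 ± 0.18 and RLTR46B at -1.50 ± 0.09 in the authors' deposited table. RLTR9A3 and RLTR19-int lay at -1.47 ± 0.10 and -1.44 ± 0.09 in the authors' deposited table. The adjusted p of all 20 selected subfamilies was at most 4.027e-07 in the authors' deposited table.

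Of the fixed lists, 2 stood apart from random lists of tested macrophage subfamilies. The MLV-like and GLN list had 8 positive and 12 negative members of 36, or 9 and 12 adjusted over the list alone, and a permutation adjusted p of 0.0012. Its mean log2 fold change was -0.24 and its median 0.03, and the permutation test with medians gave an adjusted p of 0.908, against 0.00015 to 0.0132 under the other alternatives. Narrowed after the data were seen to the viruses it was meant for, the list had 0 positive and 7 negative of 10, a median of -0.79 and a permutation adjusted p of 0.00015. Older L1 elements, ancient relatives of the active mouse L1, had 25 positive and 4 negative of 101, or 25 and 6 adjusted over the list alone, with a median of 0.04 and a permutation adjusted p of 0.011. L1MEg lay at 1.07 ± 0.08, Lx6 at 0.45 ± 0.06 and L1M3 at 0.46 ± 0.06 in the authors' deposited table. With medians in place of means the adjusted p of older L1 was 0.388, against 0.00502 to 0.0415 under the other alternatives.

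The other 13 lists in macrophages did not pass, with permutation adjusted p between 0.125 and 0.995. IAP had 7 positive and 6 negative of 25, ETn/MusD 2 and 2 of 10, MERVK10C 3 and 1 of 13, RLTR9/13/17 8 and 9 of 51, MERVL/MT2 3 and 2 of 8, ORR1 and MT MaLR 15 and 16 of 101, and VL30 0 and 2 of 5. L1Md had 8 and 4 of 31, SINE B1 0 and 0 of 15, SINE B2/B3/B4 2 and 0 of 12, DNA transposons 13 and 11 of 124, satellites 0 and 0 of 4, and structural RNA repeats 4 and 1 of 56. Adjusted over the list alone, none of these counts differed by more than 3. The 2 positive rows of the SINE B2/B3/B4 list were the ID elements ID4 and ID, at 0.14 ± 0.04 and 0.13 ± 0.05 in the authors' deposited table. IAPEY4_I-int, an IAP row on the negative side, lay at -0.71 ± 0.09, and RLTR6-int, the internal part of VL30 elements, at -1.27 ± 0.08 in the authors' deposited table. The MaLR rows ORR1A1-int at -1.05 ± 0.08, MTD-int at -0.78 ± 0.08 and MTEa-int at -0.71 ± 0.07 had the smallest adjusted p of their list in the authors' deposited table. MER57C2, an LTR element by class that the DNA transposon list took in by name, lay at -1.32 ± 0.16, and Arthur1B, a DNA transposon, at -1.19 ± 0.14 in the authors' deposited table. Median, mean and test value did not share a sign for 11 lists, which were IAP, ETn/MusD, MERVK10C, MERVL/MT2, ORR1 and MT MaLR, MLV-like and GLN, SINE B1, SINE B2/B3/B4, DNA transposons, satellites and structural RNA repeats.

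Among the subfamilies given whatever their result, MERVL-int and MT2_Mm lay at 0.49 ± 0.09 and 0.14 ± 0.05 in macrophages, and ETnERV2-int at 0.38 ± 0.09, in the authors' deposited table. MMETn-int lay at -0.64 ± 0.09, RLTR6_Mm at -0.50 ± 0.12 and IAPLTR2_Mm at 0.19 ± 0.07 in the authors' deposited table. MMERVK10C-int, MMVL30-int, B1_Mm, B2_Mm2, GSAT_MM and ORR1A0 did not pass. Their values in the authors' deposited table were -0.14 ± 0.09, -0.16 ± 0.12, -0.08 ± 0.06, -0.07 ± 0.07, -0.32 ± 0.36 and 0.17 ± 0.08, in that order.

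**Figure D2:**
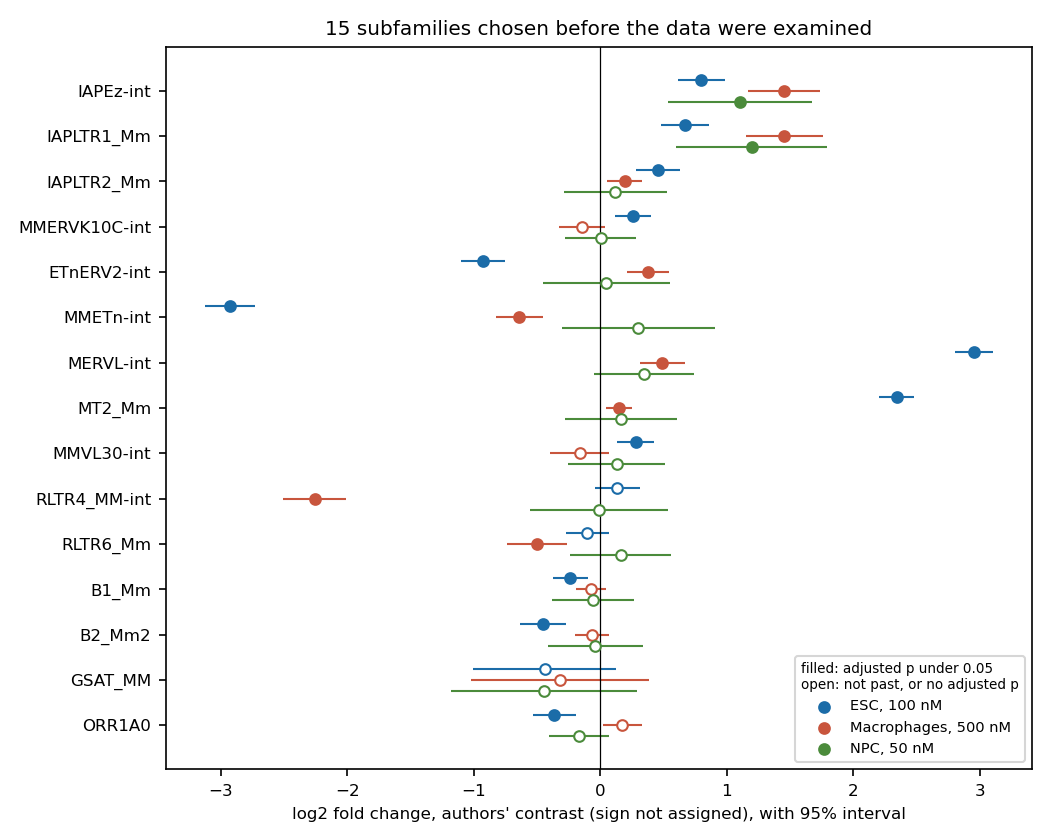
Log2 fold change of the authors' contrast (x axis, log2 units, sign not assigned to a group) for 15 repeat subfamilies chosen before the data were examined, in ESCs, macrophages and NPCs, with 95% intervals from the authors' standard errors. Filled points passed an adjusted p of 0.05 and open points did not or had none; MERVL-int lies at 2.95 in ESCs, 0.49 in macrophages and 0.34 in NPCs.

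In NPCs, IAP elements stood at the positive end and the pair RNERVK23-int and RLTR30D_RN again at the negative end. IAPA_MM-int, IAP1-MM_I-int and IAPLTR3-int lay at 2.62 ± 0.33, 2.46 ± 0.19 and 2.17 ± 0.20 in the authors' deposited table, differences of 6.15-fold, 5.50-fold and 4.51-fold at base means of 130, 913 and 365. IAP1-MM_LTR and IAPLTR4 lay at 2.08 ± 0.21 and 1.76 ± 0.33 in the authors' deposited table. RNERVK23-int lay at -4.57 ± 0.34 (23.7-fold) and RLTR30D_RN at -3.77 ± 0.34 (13.6-fold), at base means of 1012 and 1441, in the authors' deposited table. Of 1249 subfamilies tested there 147 passed, 62 positive and 85 negative, and 257 had an unadjusted p under 0.05. Beyond 1 on the log2 scale lay 61, of which 26 were positive and 35 negative. The median standard error at a base mean of at least 50 was 0.21, against 0.11 in ESCs and in macrophages, so that many changes of the size called in those tables were not detectable at this precision.

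DNA transposons took several of the remaining places among the named NPC subfamilies. As a class they were not called more often than others: 14 were positive and 19 negative of 263 tested (12.5%), against 11.8% of all tested rows. MamTip2b and Tigger16a lay at 2.14 ± 0.25 and 1.59 ± 0.17, with base means of 1070 and 1037, in the authors' deposited table. Charlie15a lay at -2.64 ± 0.25 (6.25-fold), MER102c at -1.93 ± 0.26, X6a_DNA at -1.51 ± 0.25 and MER113A at -1.39 ± 0.24 in the authors' deposited table. The LTR elements ERVB4_1-I_MM, LTR37B and RLTR20B5_MM lay at 2.05 ± 0.21, 1.93 ± 0.19 and 1.87 ± 0.22 in the authors' deposited table. HERV16-int, RLTR13D1 and MLT1J1-int lay at -1.87 ± 0.26, -1.80 ± 0.22 and -1.69 ± 0.29, and MamSINE1, a tRNA-derived element, at -1.53 ± 0.26 in the authors' deposited table. The adjusted p of all 20 was at most 3.898e-06 in the authors' deposited table.

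IAP was the single fixed list that stood apart in NPCs, with 10 positive and 1 negative of 25, or 11 and 2 adjusted over the list alone. Its median was 0.32 and its permutation adjusted p 0.00015. The 14 others had a permutation adjusted p between 0.622 and 0.995. ETn/MusD had 0 positive and 0 negative of 10, MERVK10C 0 and 2 of 13, RLTR9/13/17 4 and 4 of 51, MERVL/MT2 0 and 1 of 8, ORR1 and MT MaLR 1 and 7 of 97, VL30 1 and 0 of 5, and MLV-like and GLN 3 and 6 of 36. L1Md had 0 and 1 of 31, older L1 1 and 6 of 101, SINE B1 0 and 0 of 15, SINE B2/B3/B4 0 and 0 of 12, DNA transposons 8 and 6 of 124, satellites 0 and 0 of 5, and structural RNA repeats 3 and 1 of 55. Adjusted over the list alone, none of these counts differed by more than 3. L1MdFanc_I, the L1Md member that passed, lay at -1.29 ± 0.16 (2.45-fold, base mean 11836), and MMERGLN-int, the internal part of GLN retroviruses, at -1.35 ± 0.25 in the authors' deposited table. Median, mean and test value did not share a sign for RLTR9/13/17, MLV-like and GLN, SINE B2/B3/B4 and structural RNA repeats.

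Of the subfamilies given whatever their result, IAPEz-int and IAPLTR1_Mm passed in NPCs, at 1.10 ± 0.29 and 1.20 ± 0.30 in the authors' deposited table. The 13 others did not. MERVL-int and MT2_Mm had values of 0.34 ± 0.20 and 0.16 ± 0.23, ETnERV2-int and MMETn-int 0.05 ± 0.26 and 0.30 ± 0.31, and RLTR4_MM-int -0.01 ± 0.28 in the authors' deposited table. IAPLTR2_Mm, MMERVK10C-int, MMVL30-int and RLTR6_Mm had values of 0.12 ± 0.21, 0.00 ± 0.14, 0.13 ± 0.20 and 0.16 ± 0.20 in the authors' deposited table. B1_Mm, B2_Mm2, ORR1A0 and GSAT_MM had values of -0.06 ± 0.17, -0.04 ± 0.19, -0.17 ± 0.12 and -0.44 ± 0.38 in the authors' deposited table.

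**Figure D3:**
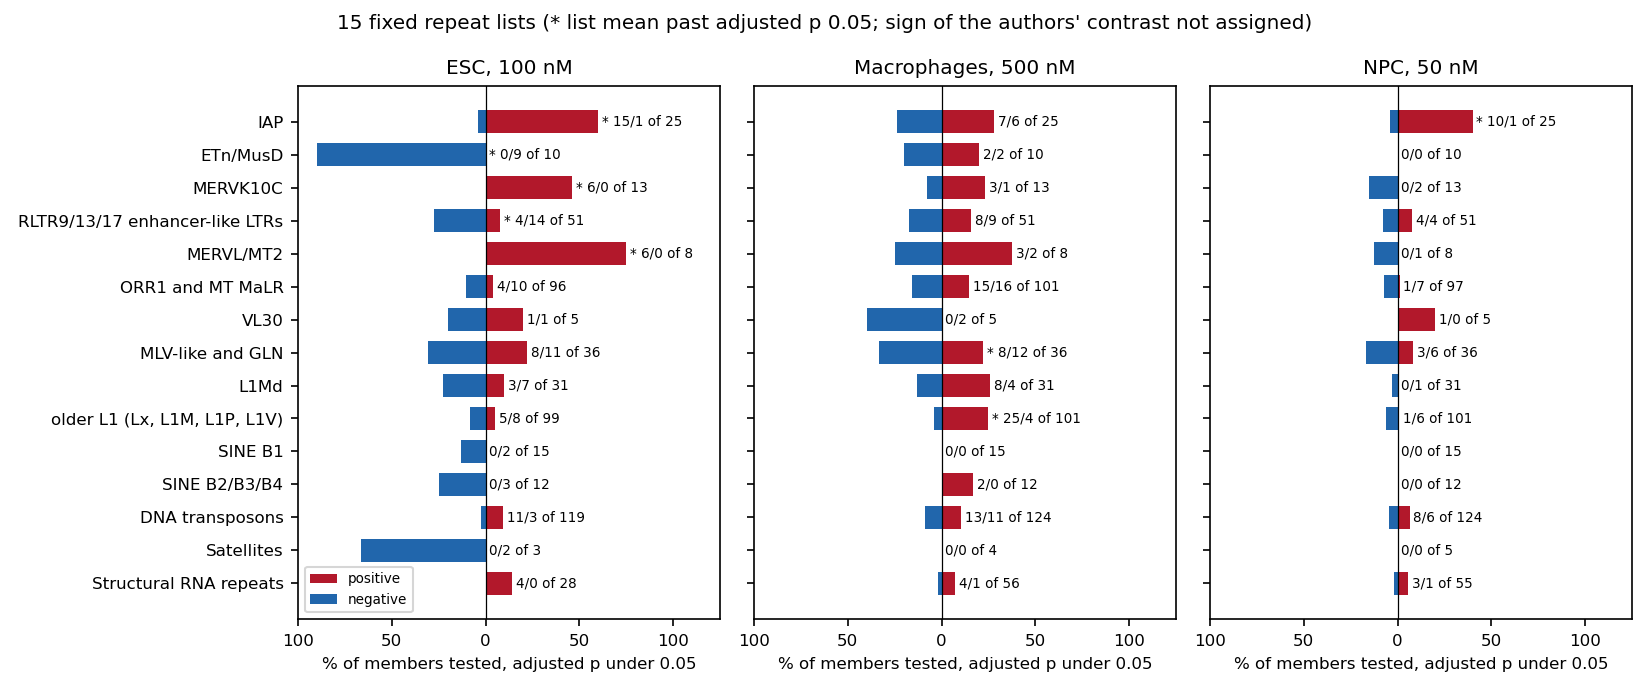
Percent of each fixed list's tested members that passed an adjusted p of 0.05 on the positive side (red, right) and the negative side (blue, left) of the authors' contrast, which is not assigned to a group, with counts beside the bars as positive/negative of tested. A star marks lists past the permutation test; of the ETn/MusD rows 9 of 10 were negative in ESCs, and of the IAP rows 15 of 25 were positive in ESCs and 10 of 25 in NPCs.

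Since the series is about endogenous retroviruses, LTR subfamilies were compared with LINE, SINE and DNA transposon subfamilies for the share called on each side (Fisher's exact test, two-sided, adjusted over 6 tests). In ESCs 87 of 625 LTR subfamilies (13.9%) were positive against 24 of 448 others (5.36%), an odds ratio of 2.86 with an adjusted p of 2.208e-05. On the negative side the counts were 97 (15.5%) against 32 (7.14%), an odds ratio of 2.39 with an adjusted p of 4.950e-05 by Fisher's exact test. In macrophages LTR subfamilies were more often negative, 113 of 649 (17.4%) against 42 of 493 (8.52%), with an odds ratio of 2.26 and an adjusted p of 3.431e-05. On the positive side of macrophages, 97 (14.9%) stood against 64 (12.98%), with an odds ratio of 1.18 and an adjusted p of 0.415. In NPCs 43 of 645 LTR subfamilies (6.67%) were positive against 16 of 492 others (3.25%), an odds ratio of 2.12 with an adjusted p of 0.0153. The negative side of NPCs gave 49 (7.60%) against 31 (6.30%), an odds ratio of 1.22 with an adjusted p of 0.415. Most called LTR rows in ESCs were ERVK, with 58 positive and 58 negative of 274. ERV1 had 12 and 22 of 111, ERVL 12 and 6 of 106, ERVL-MaLR 4 and 10 of 98 and other LTR rows 1 and 1 of 36. LINE rows had 10 and 17 of 182, SINE rows 0 and 5 of 39 and DNA transposon rows 14 and 10 of 227. Rows with low base means were called less often, and the test did not account for base mean. Related LTR subfamilies are not independent, and differences of these odds ratios between sides or cell types were not tested.

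Differences between cell types were computed with the 3 tables taken as oriented alike, which the sources used here do not state. Taken so, the contrast of ESCs stood apart from both others in MERVL-int, that of macrophages in RLTR4_MM-int, and all 3 differed from each other in MMETn-int. With the sign of 1 table of a pair turned, the ESC differences in MERVL-int and the macrophage differences in RLTR4_MM-int still passed. Between macrophages and NPCs, MMETn-int then no longer passed (-0.34 ± 0.32, adjusted p of 0.547) and MERVL-int did (0.83 ± 0.22, adjusted p of 0.00184), computed from the authors' deposited table of each. Passing in this way did not mean that the direction held. With the macrophage table turned, RLTR4_MM-int lay at -2.12 ± 0.16 as ESC minus macrophage, computed from the authors' deposited table of each. Turning the ESC table instead would give each turned difference the opposite sign. The values that follow are for tables oriented alike. Tested directly, MERVL-int lay 2.46 ± 0.12 higher on the log2 scale in the ESC than in the macrophage contrast and 2.61 ± 0.22 higher than in the NPC contrast, by values of the authors' deposited table for each. MMETn-int lay at -2.93 in ESCs, -0.64 in macrophages and 0.30 in NPCs in the authors' deposited table of each, and each pair of cell types differed, with adjusted p of 1.965e-60 for ESCs and macrophages, 4.656e-21 for ESCs and NPCs and 3.349e-02 for macrophages and NPCs. For RLTR4_MM-int, at -2.26 in macrophages, the difference was 2.39 ± 0.16 as ESC minus macrophage and -2.24 ± 0.31 as macrophage minus NPC, computed from the authors' deposited table of each. The difference did not pass for MERVL-int between macrophages and NPCs (0.14 ± 0.22, adjusted p of 0.785) or for RLTR4_MM-int between ESCs and NPCs (0.15 ± 0.29, adjusted p of 0.854), from the authors' deposited table of each. Over all rows tested in both, 266 of 1124 subfamilies differed between ESCs and macrophages, 133 with the larger value on each side. ESCs and NPCs differed in 142 of 1126, 73 with the larger value in ESCs and 69 in NPCs, and macrophages and NPCs in 151 of 1222, 76 and 75. With 1 table turned the counts were 314, 182 and 243, and 133, 68 and 74 subfamilies differed either way. These counts include subfamilies called in both tables on opposite sides, which were 34 for ESCs and macrophages, 15 for ESCs and NPCs and 15 for macrophages and NPCs. With 1 table turned, the subfamilies on opposite sides would be the other 72 of 106, 37 of 52 and 44 of 59 called in both. MuLV-int lay at 0.27 ± 0.09 in ESCs and -1.997 ± 0.109 in macrophages, MERVK26-int at -0.42 ± 0.10 and 1.53 ± 0.14, in the authors' deposited table of each. ERVB4_1C-LTR_Mm lay at -2.81 ± 0.10 in ESCs and 0.52 ± 0.19 in NPCs, and IAPLTR3-int at -0.29 ± 0.07 in macrophages and 2.17 ± 0.20 in NPCs, in the authors' deposited table of each. Dose, and for macrophages strain, differed along with the cell type, so that these cannot be told apart.

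With the tables taken as oriented alike, part of the called subfamilies was shared. On the positive side of all 3 contrasts were 7 subfamilies: IAPEz-int, IAPLTR1_Mm, IAP1-MM_I-int, IAP1-MM_LTR, RLTR44E, Tigger16a and X7C_LINE. IAP1-MM_I-int lay at 1.32 ± 0.09 in ESCs, 1.05 ± 0.15 in macrophages and 2.46 ± 0.19 in NPCs, and Tigger16a, a DNA transposon, at 0.95 ± 0.16, 0.79 ± 0.15 and 1.59 ± 0.17, in the authors' deposited table of each. With any 1 table turned, at most 3 would be shared on the positive and 4 on the negative side of the others. As deposited, on the negative side of all 3 were 15, among them RNERVK23-int, RLTR30D_RN, RLTR11A, MMERGLN-int and L1MdFanc_I. L1MdFanc_I, an L1 element with base means of 27338, 12766 and 11836, lay at -0.55 ± 0.07, -0.49 ± 0.07 and -1.29 ± 0.16 in the authors' deposited table of each. Pairwise, ESCs and macrophages shared 26 positive and 46 negative subfamilies, against 16.5 and 18.8 for independent lists (Fisher's exact test, two-sided, adjusted over 12 overlaps, p of 0.0224 and 1.195e-09). ESCs and NPCs shared 13 and 24 against 5.87 and 10.0, with adjusted p of 0.0129 and 5.212e-05 by Fisher's exact test. Macrophages and NPCs shared 18 and 26 against 8.37 and 10.9, with adjusted p of 0.00259 and 3.225e-05 by the same exact test. Fisher's exact test takes subfamilies as independent, while related rows can share reads, such as IAP1-MM_I-int and IAP1-MM_LTR or IAPEz-int and IAPLTR1_Mm. It also did not account for base mean, and rows with low base means were called less often. The p-values of these overlaps may thus be too small. None of the 6 overlaps of opposite sides, which would be the shared sides with 1 table turned, passed Fisher's exact test, with adjusted p of at least 0.549. They held 18 and 16 subfamilies for ESCs and macrophages, 9 and 6 for ESCs and NPCs and 8 and 7 for macrophages and NPCs. Restricted to base means of at least 50 in both tables, the 9 positive subfamilies shared by ESCs and NPCs gave an unadjusted p of 0.0502 by Fisher's exact test, against 0.00536 as deposited. The unadjusted p was 0.00536 with centring, 0.0204 among subfamilies at an adjusted p under 0.01, and 0.849 with 1 table turned, by the same exact test.

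Over all subfamilies with a base mean of at least 50 in both tables, log2 fold changes of different cell types were weakly related, and the sign of each relation would turn with 1 table. Across 743 subfamilies, ESC and macrophage values had a Pearson r of 0.29 and a Spearman rho of 0.18, both with a permutation p of 1e-05, the smallest that 100000 permutations can give, and 1.5e-05 adjusted over 6 correlations. Across 763, ESC and NPC values had an r of 0.17 and a rho of 0.12, with permutation adjusted p of 6e-05 and 0.00121. Across 723, macrophage and NPC values had an r of 0.43 and a rho of 0.19, both with a permutation adjusted p of 1.5e-05. Without the 2 subfamilies farthest from the median on the x axis, r was 0.30, 0.19 and 0.24, so that part of the macrophage and NPC relation rested on RNERVK23-int and RLTR30D_RN. These are relations across subfamilies, which are not independent replicates.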

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

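The test of shared ETn reads was chosen after its result was seen; the tests of differences between cell types were planned. What singled out the values here is a difference between cell types that passed an adjusted p of 0.05 when tested itself. In number, 266 subfamilies differed between ESCs and macrophages, 142 between ESCs and NPCs, and 151 between macrophages and NPCs. Differences are on the log2 scale and computed from the authors' deposited table of each cell type, and the sign of the contrast is not assigned to a group. They take the tables as oriented alike, which is not settled; with the sign of 1 table of a pair turned, an alternative added after the data were seen, the counts were 314, 182 and 243. Dose differed with cell type throughout, and strain did for macrophages, so none of these differences can be laid to cell type alone.

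Of the subfamilies given whatever their result, 12 differed between ESCs and macrophages. ESC minus macrophage, the difference was 2.46 for MERVL-int, 2.20 for MT2_Mm, 2.39 for RLTR4_MM-int, 0.44 for MMVL30-int, 0.40 for MMERVK10C-int and 0.40 for RLTR6_Mm. It was -2.29 for MMETn-int, -1.30 for ETnERV2-int, -0.79 for IAPLTR1_Mm, -0.65 for IAPEz-int, -0.54 for ORR1A0 and -0.38 for B2_Mm2. With the macrophage table turned, MMVL30-int (0.11 ± 0.14), MMERVK10C-int (0.11 ± 0.12) and ORR1A0 (-0.19 ± 0.12) no longer passed, and the 9 others did. Of these 9, some changed sign: IAPEz-int to 2.25 ± 0.17, IAPLTR1_Mm to 2.12 ± 0.18, RLTR4_MM-int to -2.12 ± 0.16 and RLTR6_Mm to -0.60 ± 0.15. The rest kept theirs. Turning the ESC table instead would give each turned difference the opposite sign. ESCs differed from NPCs in 4 of the subfamilies given whatever their result. ESC minus NPC, the difference was 2.61 for MERVL-int, 2.18 for MT2_Mm, -3.23 for MMETn-int and -0.97 for ETnERV2-int; all 4 also passed with 1 table turned. Macrophages differed from NPCs in 3: macrophage minus NPC, the difference was -0.94 for MMETn-int, -2.24 for RLTR4_MM-int and -0.66 for RLTR6_Mm. With the NPC table turned, of these RLTR4_MM-int alone passed, at -2.27 ± 0.31, while MMETn-int had -0.34 ± 0.32 and RLTR6_Mm -0.34 ± 0.24. Turned, 2 further subfamilies given whatever their result passed between ESCs and macrophages, 3 between ESCs and NPCs and 3 between macrophages and NPCs. The standard errors of the NPC table were larger, so that a smaller number of differences from NPCs does not show closer values.

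The ETn and MusD rows, of which 9 of 10 were negative in ESCs, are related in sequence and could be counting the same reads. If all shared the reads of a single set of transcripts in full, their log2 fold changes would be alike within error. They spanned 3.05 log2 units in the ESC table, from -2.95 for ETnERV-int to 0.10 for ERVB7_3-LTR_MM. Their base means ran from 115 for ERVB7_3-LTR_MM to 81651 for MMETn-int. This span counts against full sharing as the whole account. A chi-square test of heterogeneity gave p = 1.597e-229, but it was chosen after the span was seen, so it adds no support of its own. It also takes the rows as independent. Sharing within a part of the group, such as MMETn-int and ETnERV-int at -2.93 and -2.95, stays open, since no values per copy were used here. The difference between untreated ESC libraries and those treated at 100 nM is what the authors' contrast tests, and these 9 rows passed it. Whether it is particular to ESCs or to this dose cannot be told apart.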

How the results depend on the processing

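Random lists matched on base mean, narrowed name patterns and turning the sign of 1 table of a pair were chosen after the data were seen; all other alternatives were planned. No paired analysis was possible because the tables hold no values per library. For the same reason another normalisation or count model, other pseudocounts, leaving out replicates, and other splits of the libraries could not give a value and were not run, so that how far single libraries carry these results is open. Of the values that answer a comparison, 73 alternatives left the call, or the count within 1.5 times, and 17 did not. The 17 were all counts. Requiring a log2 fold change beyond 1 left 36 subfamilies in ESCs, 53 in macrophages and 61 in NPCs, against 251, 324 and 147. At an adjusted p under 0.01, 95 were left in NPCs, 91 differences between macrophages and NPCs, 16 positive and 30 negative shared subfamilies for ESCs and macrophages, 7 and 12 for ESCs and NPCs, and 17 negative for macrophages and NPCs. These losses follow from the stricter thresholds. With the sign of 1 table turned, 243 subfamilies differed between macrophages and NPCs, and the shared negative ones were 16 for ESCs and macrophages and 6 for ESCs and NPCs; macrophages and NPCs shared 8 and 7. Leaving out each list's member of largest absolute change left 3 lists past the test in ESCs, against 5. With medians in place of means, 0 lists passed the permutation test in macrophages, against 2, while 2 lists, RLTR9/13/17 and L1Md, had an unadjusted permutation p under 0.05; the MLV-like and GLN list, past the test with a negative mean, had a median test value of 0.24, since its members went both ways.

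Among single lists, 7 alternatives ended a call with the direction kept, for MERVK10C and RLTR9/13/17 in ESCs and older L1 in macrophages. The median also ended the call of MLV-like and GLN in macrophages, with the sign turned, and 1 alternative, the median for satellites in ESCs, made a call. Satellites in ESCs without their largest member gave no value, since 2 members were left. The calls of IAP, ETn/MusD and MERVL/MT2 in ESCs, and of IAP in NPCs, held under all 6 alternatives run for lists. Named subfamilies held their side and call in each of the 98 cases under centring, 98 under adjustment over every row with a p, 98 without structural RNA rows and 96 under a base mean minimum of 50. These alternatives could hardly move them. A new adjustment leaves the side as it was, and the medians used for centring were 0.0019, -0.0129 and 0.0009 in ESCs, macrophages and NPCs. Subfamilies selected by the naming rule had an adjusted p of at most 3.898e-06 in the authors' deposited table of each. Counts with adjustment over every row were 234, 320 and 141, and with centring 252, 319 and 149, in the order ESCs, macrophages and NPCs. Low rows were called less often, and whether depth sets this was not tested: among tested rows with a base mean under 50 the called share was 9.93% in ESCs, 9.26% in macrophages and 5.82% in NPCs, against 26.05%, 36.3% and 15.3% at 50 or more.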

Other observations

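The subfamily groups in this paragraph and the next were picked after their values were seen, and so were the tests of orientation and of the pair of rows; the test of LTR and internal rows was set before its result was seen. All 6 RLTR44 rows, which belong to the ERVK class, were positive in ESCs, from 0.63 ± 0.13 (SE) for RLTR44E to 2.75 ± 0.17 for RLTR44D in the authors' deposited table. In macrophages 5 of the 6 were positive, among them RLTR44-int at 0.72 ± 0.13 in the authors' deposited table. In NPCs 1 of the 6 was, RLTR44E at 0.95 ± 0.28 in the authors' deposited table. MER89, with the largest positive value in ESCs, had values of -0.43 ± 0.22 in macrophages and -0.03 ± 0.28 in NPCs in the authors' deposited table of each, and neither passed.

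Of 23 internal ERV1 rows in macrophages, 10 were negative, 0 positive and 13 not past the authors' DESeq2 adjusted p of 0.05, with a median of -0.31. At an unadjusted p under 0.05, 1 was positive, RodERV21-int at 0.23 ± 0.11 in the authors' deposited table. Of 93 ERV1 LTR rows 9 were positive and 18 negative, and whether internal and LTR rows differ was not tested. In ESCs 3 of 23 ERV1 internal rows were positive and 6 negative, and in NPCs 0 and 1, with 1 positive at an unadjusted p under 0.05, MER34-int at 0.84 ± 0.31 in the authors' deposited table. LINE rows in macrophages were positive in 39 of 190 and negative in 17. In ESCs the LINE counts were 10 and 17 of 182, and in NPCs 2 and 11 of 190. The short interspersed elements B2_Mm1a and B2_Mm1t passed on the negative side in ESCs, and had values of -0.32 ± 0.17 and -0.25 ± 0.14 in macrophages and -0.78 ± 0.32 and -0.58 ± 0.29 in NPCs in the authors' deposited table of each. Differences between cell types were not tested for these counts.

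A candidate explanation for contrasts that disagree in sign is that a table was built with the groups the other way round. If effects are shared between cell types, a table so built would agree in sign with the others in under 50% of subfamilies called in both. The share was 67.9% of 106 for ESCs and macrophages (exact 95% interval 58.2 to 76.7%), 71.2% of 52 for ESCs and NPCs (56.9 to 82.9%) and 74.6% of 59 for macrophages and NPCs (61.6 to 85.0%). These shares restate the overlaps of called subfamilies. Whatever the sign, RNERVK23-int and RLTR30D_RN had the largest absolute values among the named subfamilies of both macrophages and NPCs. Such values show that the same rows differed in both, but not that effects share a direction. The shares therefore do not decide whether a table was turned round. The intervals also take related rows as independent. The sign of every value stays unassigned.

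RNERVK23-int and RLTR30D_RN, far on the negative side in each table, may be counting the reads of 1 transcript or set of copies that holds both, which these tables leave open. Their log2 fold changes differed by at most 1.65 joint standard errors over the 3 tables, reached in NPCs with -4.57 against -3.77, and their base means were within a ratio of 0.65 to 1.01 of each other. This does not speak for the explanation: the pair was picked for its alike values, and the joint error takes the rows as independent and is wide in NPCs, at 0.49. Whether such a transcript exists was not tested, since no repeat coordinates were used here. Shared reads would bear on why the 2 rows are alike, and not on the difference between treated and untreated libraries. That difference passed for both rows in each table, with an adjusted p of at most 3.548e-25 in the authors' deposited table of each.

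A hypothesis set before its test was that an LTR and the internal part of the same name report the same transcripts and so move together. Across pairs with base means of at least 50, the Pearson r of their log2 fold changes was 0.53 over 43 pairs in ESCs, 0.25 over 39 in macrophages and 0.28 over 40 in NPCs. Adjusted over 6 correlations, the permutation p were 0.00174, 0.138 and 0.138. The Spearman rho were 0.26, 0.34 and 0.22, with permutation adjusted p of 0.138, 0.109 and 0.171, and r without the 2 farthest pairs was 0.44, 0.20 and 0.09. In ESCs the Pearson correlation is what shared transcripts would give, while the rank correlation did not pass. Reads counted for both an LTR and its internal part would give such a correlation as well, and the test cannot tell these apart. In macrophages and NPCs the tests leave the hypothesis open. Pairs are not independent replicates.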
